A study of Mus musculus with 15 samples.

How the data were processed

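The samples were erythroid progenitors from fetal livers of C57BL/6 mice at E13.5, passed over magnetic columns to remove cells bearing TER119 or CD11b and cultured with erythropoietin. Per the labels, 500 ng of total RNA with an integrity number above 8 was amplified, labelled with biotin and hybridised to an Illumina bead array, 15 arrays in all. The series design gives 5 groups of 3 biological replicates, so p-values measure the spread between biological replicates. The labels number the replicates 1 to 3 in each group but do not say that a number marks a shared litter, culture or day.

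Each array comes with a raw intensity per probe, which the authors deposited without normalization on a linear scale, and with a detection p-value per probe, also deposited by the authors, which tells how often background reaches that signal. A second table holds values the authors deposited after processing. Per the submitters' processing notes BeadStudio was used, and its version is not given. The authors' processed intensities are on a linear scale, hold values below 0 and have nearly the same distribution on every array, with medians between 10.915 and 11.126, and within each array they rank the probes as the raw signals do. Apart from what these values show, the method, scale and centring are not given in the sources used here. These processed values were used as an alternative only.

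Raw intensities were processed with limma (version 3.58.1) in R (version 4.3.3). The function neqc corrected the background from the detection p-values, added an offset of 16, took log2 values and quantile-normalized the arrays. Of 25697 probes, 12053 with a detection p under 0.01 on at least 3 of 15 arrays were kept. Probe names came from the platform annotation given with the series, in which 23978 probes have 1 gene symbol, 0 have several and 1719 have none here. Symbols were checked through the mouse RefSeq gene table of assembly GRCm38.p6, used for names only, and 0 were changed. For each gene the kept probe with the highest mean was used, which gave 9046 genes to test, 698 of them probes without a symbol. Of 2145 genes with several kept probes, between 2 and 26 per comparison had probes called in both directions, and none of these is named in the text. No probe carries the symbol Kit or Hbb-b1 in this annotation, so both are not analysed here.

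A linear model with a mean for each of the 5 groups was fitted to all 15 arrays (lmFit, then eBayes with an intensity trend), and each comparison is a contrast of 2 group means with Benjamini-Hochberg adjustment over all genes tested. The comparisons were 24 h against 0 h, 48 h against 24 h and 48 h against 0 h in uninfected cells, each Myc group against uninfected cells at 48 h, and the Myc groups against each other. A gene counts as called at an adjusted p under 0.05. Where a gene was not detected on any array of a group, its fold is a bound, taken against the mean over that group's arrays of the higher of the lowest detected log2 value on the array and the gene's own value, written as at least N-fold.

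There were 33 gene lists with 786 genes. They cover globins, heme synthesis and iron uptake, red cell membrane and cytoskeleton, erythroid transcription factors, stem and progenitor genes, the Myc network, Myc-regulated metabolism and nucleotide synthesis, nucleolar ribosome biogenesis, cytosolic ribosomal proteins, translation factors, DNA replication and G1/S, mitosis and G2/M, cell cycle inhibitors, histone acetyltransferases, histone deacetylases, autophagy and organelle clearance, enucleation and nuclear export, apoptosis, oxidative phosphorylation, glycolysis, mitochondrial biogenesis and import, the unfolded protein and amino acid stress response, interferon response, immediate early and heat shock genes, and targets of erythropoietin signalling. The others are markers of macrophages, granulocytes, megakaryocytes, mast cells, hepatocytes, endothelium, mesenchyme and lymphoid cells. Each was tested with limma's camera (preset correlation 0.01), adjusted over the lists of a comparison, and again with an estimated correlation. The estimated correlation left 66 list results without their call. Calls that hold with it are those of heme synthesis, membrane, nucleolar, mitosis and cell cycle inhibitor lists for 24 h against 0 h, of Myc-regulated metabolism, nucleolar, DNA replication, cell cycle inhibitor, autophagy and interferon lists for 48 h against 24 h, and of nucleolar, cell cycle inhibitor and autophagy lists for 48 h against 0 h. In the moderate group they are interferon, macrophage, granulocyte and mast cell lists. In the high group they are these 4 and the Myc-regulated metabolism, nucleolar, mitochondrial biogenesis, cell cycle inhibitor, autophagy and enucleation lists, and between the Myc groups the Myc-regulated metabolism, nucleolar, cell cycle inhibitor and autophagy lists.

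Genes were named by a rule. For 48 h against 0 h and for each Myc group against uninfected cells it takes the 5 largest rises and 5 largest falls among called genes whose groups do not overlap, and for the other comparisons the 3 largest each, leaving out clone and locus identifiers (1 was passed over in each of 2 comparisons). It adds the up to 4 called members of each list with the largest change, and a fixed set given in every comparison: Myc, Cdkn1b, Kat2a, Kit, Gata1, Klf1, Gata2, Myb, Hdac2, Ccnd2, Ccnd3, Cdkn2c, Bcl2l1, Alas2, Slc4a1, Hba-a1 and Hbb-b1, with Hbb-bt for Hbb-b1. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, except where a choice is said to have been made after, such as the comparison of the high group with uninfected cells at 24 h.

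The maturation index and the share of genes of opposite sign use genes called for 24 h against 0 h with at least a 2-fold change. Index differences were tested with a two-sided exact permutation test, whose smallest p for 3 against 3 is 0.1. Correlations and covariances between the Myc groups were set beside 100 simulations of unchanged groups against the same uninfected arrays, and overlaps beside the number that independent lists would share. The model was tested on simulated data with 9046 genes and known changes. For 24 h against 0 h it called 191 genes, 14 of them wrongly, and recovered 79% of genes changed 2-fold and 98% of those changed 4-fold, with similar values for 48 h against 24 h (183, 7, 77% and 99%).

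Alternatives were quantile normalization without background correction, scaling by the 75th percentile without quantile normalization, the authors' processed values, an offset of 50, no detection filter, detection on all 15 arrays, the mean of a gene's probes, the replicate number as a block, no intensity trend, array weights, a fit of the 2 groups alone, fry and an estimated correlation for lists, and leaving out each array in turn. The number of arrays and the signal over background limit the precision.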

Results

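Erythroid progenitor cells were taken from the livers of C57BL/6 mouse embryos at E13.5, the site and stage at which the embryo makes most of its red cells. Cells carrying TER119, a surface protein of maturing red cells, or CD11b, a surface protein of myeloid cells, had been removed with magnetic beads. The remaining cells were cultured with erythropoietin, the hormone that drives red cell formation. RNA was measured on 15 Illumina bead arrays in 5 groups of 3 biological replicates. Uninfected cells were taken at 0, 24 and 48 h of culture. The other 2 groups were infected at 0 h with a retrovirus that carries Myc, a transcription factor that drives growth and proliferation, together with green fluorescent protein (GFP). At 48 h they were sorted for moderate GFP, which the labels call a physiological level of Myc, or for high GFP, called supraphysiological. The uninfected cells were not sorted, and no group received an empty virus. Infection, sorting and Myc differ together between the Myc groups and the uninfected cells.

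Each array read 25697 probes. Between 9057 and 11105 probes per array, 35.2% to 43.2%, were detected above background, and the median raw signal per array lay between 68.2 and 102. Pairs of arrays of one group correlated across genes at r between 0.979 and 0.995 (genes are not independent replicates). The highest raw signals of the arrays numbered 3 (58055 to 60908) lay apart from those numbered 1 (42017 to 45167) and 2 (43260 to 46494). Each number holds 1 array of every group. The sign ± after a log2 difference is its standard error in limma with 3 arrays per group. A gene is said to rise, fall or change where its adjusted p is under 0.05. A gene named as not detected in a group has only a bound on its fold there.

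Myc itself, the transferred gene, was read by 1 detectable probe whose log2 level hardly differed between groups. It was 6.94 ± 0.19 (SD, n = 3) in uninfected cells at 0 h, 6.62 ± 0.56 at 24 h and 6.77 ± 0.62 at 48 h, against 7.21 ± 0.24 in the moderate and 6.84 ± 0.40 in the high group. No comparison of groups passed the test. Relative to uninfected cells at 48 h the difference was 0.44 ± 0.30 for the moderate group (adjusted p = 0.283) and 0.07 ± 0.30 for the high group (adjusted p = 0.867). A second Myc probe was detected on 0 of 15 arrays, and whether either probe can read the retroviral transcript is not given in the sources used here. The arrays therefore do not measure how much Myc each group received. Among Myc's partners and antagonists, Mxd1, which competes with Myc for its partner Max, was not detected at 0 h or 24 h and was at least 4.95-fold higher at 48 h than at 0 h. Mxi1, another antagonist, rose by 1.93 ± 0.18 from 0 h to 48 h.

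**Figure D1:**
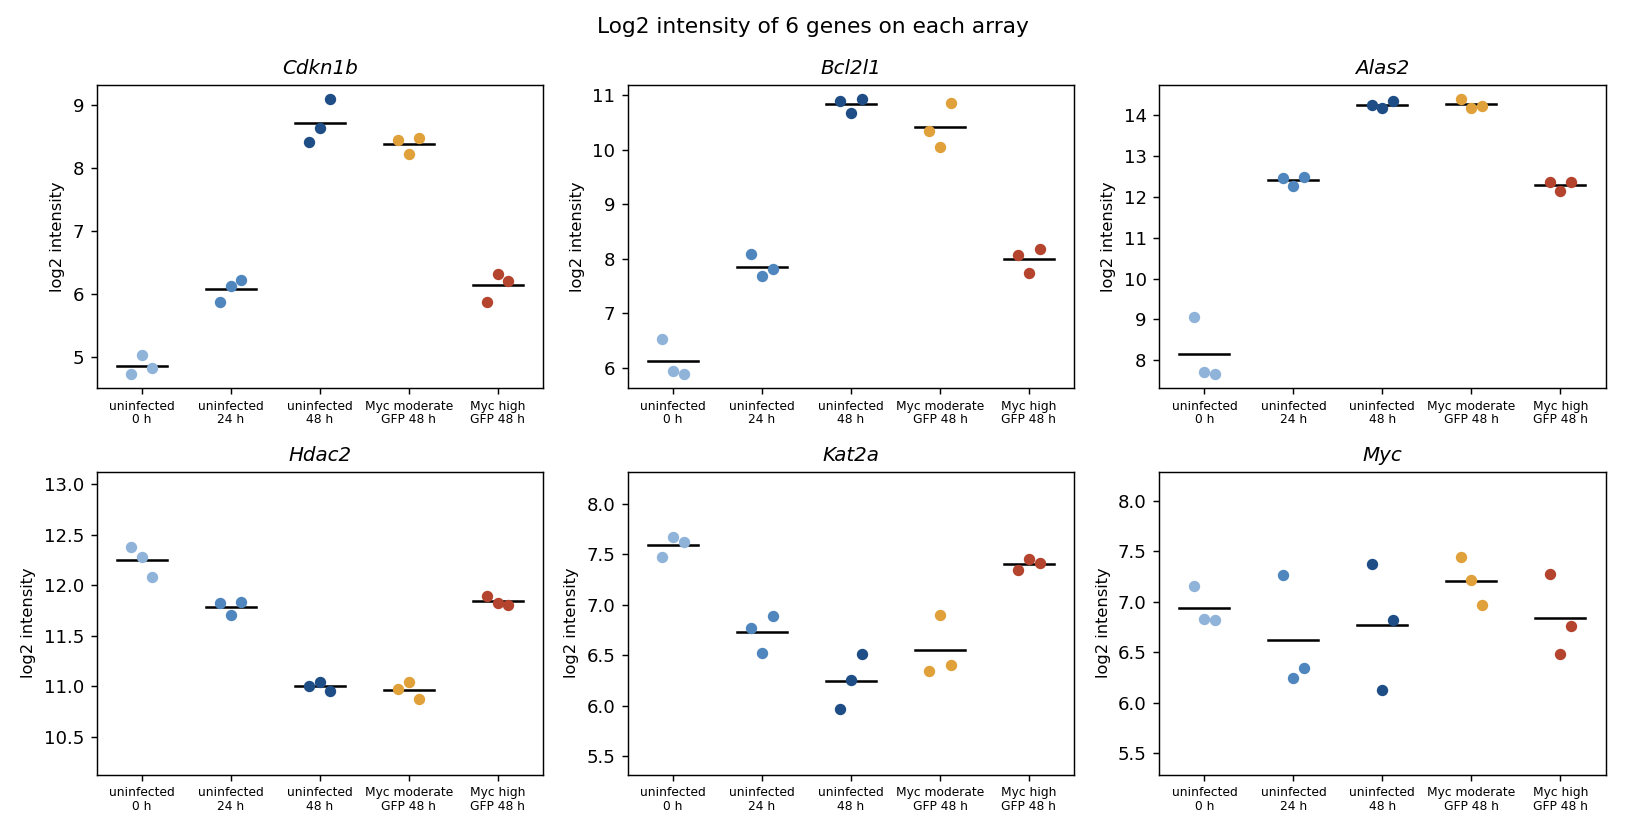
Log2 intensity of 6 genes on each of the 15 arrays by group, with points for single arrays and a line at each group mean (n = 3). Cdkn1b, Bcl2l1 and Alas2 have log2 means of 6.14, 8.00 and 12.29 in the high group and 8.72, 10.84 and 14.25 in uninfected cells at 48 h.

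During the first 24 h of culture, uninfected cells turned on the machinery of the red cell. Alas2, the first enzyme of erythroid heme synthesis, rose by 4.27 ± 0.23 (adjusted p = 6.31e-11), and Slc4a1, the anion exchanger of the red cell membrane, by 2.15 ± 0.19. Myb, a transcription factor of progenitors, fell by 1.60, and Cd34, a progenitor surface protein, by 1.19. Ribosome-making genes fell and mitosis genes rose in the same interval. In limma, 1358 genes rose and 1585 fell (46.1% higher), out of 9046 tested. Of these 750 changed at least 2-fold, 463 up and 287 down, a count of 360 without background correction, 482 with an offset of 50 and 404 with genes detected on all 15 arrays. Under 75th percentile scaling 1509 rose and 1333 fell (53.1% higher), so which direction held more genes depends on the scaling. The groups did not overlap for 4095 genes (45.3%), where chance gives 10%. Without the 5 arrays numbered 3, an alternative added after the data were seen, 1794 genes were called. The largest rises were those of Gpnmb, a glycoprotein abundant in macrophages, not detected at 0 h and at least 186-fold higher at 24 h, of Csta2, a protease inhibitor of the stefin family (5.23 ± 0.27, detected on 1 of 3 arrays at 0 h), and of Lgals3, a galectin (4.88 ± 0.23). The largest falls were those of Ttr, a transport protein secreted by liver cells, at least 26.8-fold lower and not detected at 24 h, of the fetal growth factor Igf2 (-5.18 ± 0.43) and of the lipoprotein Apoa2 (-5.18 ± 0.42, detected on 1 of 3 arrays at 24 h).

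Genes of heme synthesis and of the red cell membrane rose between 0 h and 24 h. Of 15 measured genes of heme synthesis and iron uptake, 14 rose and 0 fell (14 and 0 adjusted over the list alone), such as Uros (2.00 ± 0.14) and Fech (1.84 ± 0.13), which both act in the heme pathway. The heme list had a camera adjusted p of 1.22e-11, and 0.0388 with an estimated correlation. Among 17 genes of the red cell membrane and cytoskeleton, 15 rose and 1 fell (15 and 2 adjusted over the list alone), with Tmod1, which caps actin filaments, at 2.58 ± 0.12 (camera adjusted p = 1.70e-10, and 0.0271 with an estimated correlation). Of 6 globin genes 4 rose and 0 fell (4 and 0 adjusted over the list alone), led by Hbb-b2 (2.90 ± 0.28) and Hbb-bh1 (2.84 ± 0.43). Their camera adjusted p was 0.0220, and 0.380 with an estimated correlation. Hba-a1 ranked between 1 and 22 in raw brightness on every array, at 74.9% or more of that array's highest signal, where bead arrays compress differences. The beta-globin gene Hbb-bt rose by 1.49 ± 0.30. The rise of Hba-a1, 0.32, was lost when any of 5 arrays was left out. Of 18 erythroid transcription factors, 9 rose and 4 fell, 9 and 4 adjusted over the list alone, among them E2f2 (1.86 ± 0.19), Nfe2 (1.53 ± 0.15) and Tal1 (1.46 ± 0.10). The factors' camera adjusted p was 0.0115, and 0.221 with an estimated correlation. Gata1, the master regulator of red cell genes, rose by 1.12 ± 0.15, and Klf1, which drives adult globin, by 0.67 ± 0.17. Of 11 stem and progenitor genes, 1 rose and 6 fell (1 and 6 adjusted over the list alone), but the list did not pass its test (camera adjusted p = 0.167).

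Growth and division genes divided between falling and rising groups. Of 37 genes of nucleolar ribosome biogenesis, 31 fell and 0 rose (34 and 0 adjusted over the list alone), including Ncl, which codes for nucleolin (-0.95 ± 0.12), and Rrp12 (-0.85 ± 0.12). The list's camera adjusted p was 1.22e-11, and 0.0388 with an estimated correlation. Genes of mitochondrial biogenesis and import fell in 13 of 26 cases and rose in 1 (15 and 1 adjusted over the list alone) (camera adjusted p = 1.35e-04, and 0.148 with an estimated correlation). In contrast, 15 of 23 mitosis and G2/M genes rose and 0 fell (17 and 0 adjusted over the list alone), among them Cdc25b, a phosphatase that starts mitosis (2.20 ± 0.21, detected on 2 of 3 arrays at 0 h), and Ube2c (1.15 ± 0.20). Camera gave an adjusted p of 4.63e-06, and 0.0271 with an estimated correlation. Cell cycle inhibitors rose in 9 of 16 cases and fell in 2 (9 and 2 adjusted over the list alone), with Gadd45a at 3.18 ± 0.12, Cdkn2c at 1.96 ± 0.18 and Cdkn1c at -2.92 ± 0.40 (camera adjusted p = 0.00240, and 0.0388 with an estimated correlation). The D-type cyclins, which move cells into S phase, changed in opposite directions. Ccnd3 rose by 1.37 ± 0.13, while Ccnd2 (-0.80 ± 0.13) and Ccnd1 (-1.64 ± 0.25) fell. Bcl2l1, which protects cells from apoptosis, rose by 1.74 ± 0.20, and Cdkn1b was not detected at 0 h and at least 1.92-fold higher at 24 h. Kat2a (-0.86 ± 0.19), Gata2 (-0.51 ± 0.13) and Hdac2 (-0.46 ± 0.09) fell, and Myc was at -0.32 ± 0.30 (adjusted p = 0.469). Of 22 genes of the unfolded protein and amino acid stress response, 13 rose and 4 fell (14 and 4 adjusted over the list alone). They include Ddit3, a transcription factor of stressed cells (3.68 ± 0.29), and Chac1 (3.36 ± 0.50), with a camera adjusted p of 2.41e-04 and 0.149 with an estimated correlation.

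Further gene groups passed their test over the first day. Autophagy and organelle clearance genes rose in 10 of 25 cases and fell in 1 (12 and 1 adjusted over the list alone), among them Ube2o (1.95 ± 0.14), which codes for a ubiquitin ligase of maturing red cells. Their camera adjusted p was 1.42e-04, and 0.0530 with an estimated correlation. Feedback targets of erythropoietin signalling through JAK and STAT proteins rose in 5 of 13 cases and fell in 0 (7 and 0 adjusted over the list alone). They include Erfe, the erythroid hormone that lowers hepcidin (2.39 ± 0.16), and Tfrc, the transferrin receptor (1.32 ± 0.11), with a camera adjusted p of 6.88e-04 and 0.137 with an estimated correlation. Of 18 glycolysis genes 5 rose and 2 fell (5 and 2 adjusted over the list alone), led by the glucose transporter Slc2a1 (2.37 ± 0.12). Camera gave an adjusted p of 0.0260, and 0.380 with an estimated correlation. Immediate early and heat shock genes fell in 5 of 15 cases and rose in 0 (8 and 0 adjusted over the list alone), for example the chaperone genes Hsph1 (-0.73 ± 0.10) and Dnajb1 (-0.48 ± 0.10). Camera gave these 0.00504, and 0.389 with an estimated correlation.

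Transcripts of other cell types also changed over the first day. Of 15 hepatocyte markers 13 fell and 0 rose (13 and 0 adjusted over the list alone), with a median of -2.04, or -1.80 with genes not detected at 24 h at their bound (camera adjusted p = 1.70e-10, and 0.149 with an estimated correlation). Serpina1b was not detected at 24 h, at least 18.9-fold below its 0 h level. Of 10 endothelial markers 8 fell and 0 rose (8 and 0 adjusted over the list alone), among them Lyve1 (at least 4.02-fold lower) and Esam (-1.47 ± 0.26), with a median of -1.24, -0.82 at the bounds (camera adjusted p = 2.41e-04, and 0.119 with an estimated correlation). Macrophage markers rose in 9 of 14 cases and fell in 0 (9 and 0 adjusted over the list alone), for example Lyz2, a lysozyme (2.85 ± 0.20), and Adgre1, a macrophage surface receptor (2.40 ± 0.21). Their camera adjusted p was 7.55e-07, and 0.0884 with an estimated correlation. Of 17 granulocyte markers 8 rose and 3 fell (8 and 4 adjusted over the list alone), with S100a9 at 3.61 ± 0.30 and Camp at 4.22 ± 0.27 (detected on 2 of 3 arrays at 0 h). The list's median was 0.60, or 0 with undetected genes at their bound (camera adjusted p = 0.0150, and 0.380 with an estimated correlation). CD11b-bearing cells had been depleted before culture.

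Between 24 h and 48 h, uninfected cells lowered the expression of DNA replication and ribosome-making genes and raised genes that stop the cell cycle and dismantle organelles. Cdkn1b, which codes for the cyclin-dependent kinase inhibitor p27, rose by 2.64 ± 0.19 (adjusted p = 3.30e-09), and Bcl2l1, the survival protein of maturing erythroblasts, by 2.98 ± 0.20 (adjusted p = 8.18e-10). Alas2 rose by a further 1.84 ± 0.23, and Hdac2, a histone deacetylase, fell by 0.79. Interferon response genes rose strongly in the same interval. In all 1285 genes rose and 2114 fell, while 567 of the 713 genes changed at least 2-fold rose and 146 fell, and 4192 genes, 46.3%, had groups that did not overlap (10% by chance). The largest rises were those of the antiviral gene Rsad2 (6.07 ± 0.21, detected on 2 of 3 arrays at 24 h), Oasl2, another interferon-induced gene (5.11 ± 0.18), and Ptpn14, a tyrosine phosphatase (4.69 ± 0.23, detected on 2 of 3 arrays at 24 h). The largest falls were those of Tnfrsf13c, a receptor known from B cells (-2.81 ± 0.29), Mrap (-2.03 ± 0.18) and Btnl10, not detected at 48 h and at least 2.23-fold lower.

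Of 33 genes of DNA replication and the G1/S transition, 31 fell from 24 h to 48 h and 0 rose (31 and 0 adjusted over the list alone). They include Mcm2, a subunit of the replicative helicase (-1.15 ± 0.11), Cdc6, which loads it (-1.21 ± 0.11), and the transcription factor E2f1 (-1.18 ± 0.13). For this list camera gave an adjusted p of 8.30e-14, and 0.0194 with an estimated correlation. Nucleolar ribosome biogenesis genes fell in 32 of 37 cases and rose in 0 (33 and 0 adjusted over the list alone), among them Bop1 (-1.11 ± 0.15) and Nop58 (-1.02 ± 0.09). Camera gave an adjusted p of 4.03e-12, and 0.0250 with an estimated correlation. Of 22 genes of Myc-regulated metabolism and nucleotide synthesis, 14 fell and 0 rose (14 and 0 adjusted over the list alone). Ctps, which makes cytidine nucleotides, changed by -1.05 ± 0.09, and Odc1, the first enzyme of polyamine synthesis, by -0.90 ± 0.09 (camera adjusted p = 1.99e-04, and 0.0187 with an estimated correlation). Oxidative phosphorylation genes fell in 19 of 35 cases and rose in 0 (19 and 0 adjusted over the list alone) (camera adjusted p = 1.99e-04, and 0.0977 with an estimated correlation). For mitochondrial biogenesis and import, 18 of 26 genes fell and 1 rose (20 and 1 adjusted over the list alone; camera adjusted p = 1.76e-05, and 0.102 with an estimated correlation).

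Genes of autophagy and organelle clearance, through which the maturing red cell removes mitochondria and other contents, rose in 16 of 25 cases between 24 h and 48 h and fell in 0 (16 and 0 adjusted over the list alone). Sqstm1, an autophagy receptor, rose by 2.83 ± 0.18, Ulk1, the kinase that starts autophagy, by 2.63 ± 0.14 and the ubiquitin ligase Ube2o by 2.55 ± 0.14. The list's camera adjusted p was 3.72e-11, and 0.00934 with an estimated correlation. Of 16 cell cycle inhibitors 8 rose and 1 fell (8 and 1 adjusted over the list alone), including Gadd45a (2.58 ± 0.12) and Ccng2 (2.10 ± 0.13), with a camera adjusted p of 2.04e-05 and 0.00934 with an estimated correlation. Among 22 genes of enucleation and nuclear export, 7 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.176), with Tmcc2 at 3.70 ± 0.24 and the exportin Xpo7 at 3.33 ± 0.17. Apoptosis regulators rose in 7 of 18 cases and fell in 0 (7 and 0 adjusted over the list alone), among them Bcl2l1 and the death-promoting Bbc3 (3.00 ± 0.39), with a camera adjusted p of 0.0115 and 0.0839 with an estimated correlation. For heme synthesis and iron uptake, 6 of 15 genes rose and 2 fell (6 and 2 adjusted over the list alone), led by Hmox1, which degrades heme (3.86 ± 0.20), at a camera adjusted p of 0.00368 and 0.279 with an estimated correlation.

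Of 21 interferon response genes 18 rose from 24 h to 48 h and 0 fell (20 and 0 adjusted over the list alone), such as Isg15 (4.24 ± 0.28) and Ifit3 (4.01 ± 0.22). The list's median rise was 1.61, or 1.46 with genes not detected at 24 h at their bound, with a camera adjusted p of 5.93e-16 and 0.0113 with an estimated correlation. Macrophage markers rose in 10 of 14 cases (10 and 0 adjusted over the list alone; camera adjusted p = 1.54e-04, and 0.180 with an estimated correlation). Granulocyte markers rose in 8 of 17 cases (8 and 0 adjusted over the list alone; camera adjusted p = 8.39e-05, and 0.211 with an estimated correlation), with Ltf, the granule protein lactoferrin, at 3.42 ± 0.29. Megakaryocyte and platelet markers rose in 6 of 16 cases (7 and 0 adjusted over the list alone; camera adjusted p = 8.03e-04, and 0.313 with an estimated correlation). Stress response genes were higher in 11 of 22 cases and lower in 3 (11 and 3 adjusted over the list alone), with Ppp1r15a at 2.30 ± 0.16 (camera adjusted p = 3.70e-04, and 0.187 with an estimated correlation). Kat2a, the histone acetyltransferase also called Gcn5, was at -0.49 ± 0.19 (adjusted p = 0.0470). That call was lost when the arrays were scaled by their 75th percentile (-0.36, adjusted p = 0.121), and when any of 4 arrays was left out. The progenitor factor Gata2 rose by 1.03 ± 0.13, and Ccnd3 fell by 0.58. Gata1 (-0.01 ± 0.15, adjusted p = 0.971), Klf1 (-0.19 ± 0.17, 0.393), Myb (0.32 ± 0.22, 0.270), Myc (0.15 ± 0.30, 0.729), Ccnd2 (0.03 ± 0.13, 0.885), Cdkn2c (0.01 ± 0.18, 0.982) and Slc4a1 (0.11 ± 0.19, 0.687) did not pass the test. Nor did Hba-a1 (-0.01 ± 0.11, adjusted p = 0.948) or Hbb-bt (0.53 ± 0.30, 0.180), though Hbb-bt passed under 75th percentile scaling (0.85, adjusted p = 0.00993) and with the replicate number as a block (adjusted p = 0.00330).

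Over the whole 48 h, uninfected cells gained autophagy and cell cycle inhibitor transcripts and lost transcripts for ribosome assembly. Macrophage markers (median 2.20, camera adjusted p = 1.86e-06, and 0.0843 with an estimated correlation) were higher on the same arrays. Alas2 rose by 6.11 ± 0.23 to a log2 level of 14.25, and Bcl2l1 by 4.72 ± 0.20. Cdkn1b was not detected at 0 h and was at least 11.98-fold higher at 48 h, while the histone acetyltransferase Kat2a (-1.35 ± 0.19) and the deacetylase Hdac2 (-1.25 ± 0.09) fell. In all 2024 genes rose and 3219 fell (38.6% higher), 2160 by at least 2-fold (1099 up, 1061 down). With the arrays scaled by their 75th percentile in place of quantile normalization, 2575 rose and 2622 fell (49.5% higher). That scaling moved the median change of all genes from -0.16 to 0.05, and from -0.11 to 0.02 for 48 h against 24 h. The groups did not overlap for 5691 genes, 62.9% (10% by chance). The largest rises were those of Gpnmb, not detected at 0 h and at least 349.8-fold higher, Ltf (7.43 ± 0.29, detected on 1 of 3 arrays at 0 h), Oasl2 (7.40 ± 0.18, detected on 1 of 3), and Rsad2 (6.65 ± 0.21, detected on 2 of 3). Lcn2, a granule protein, was not detected at 0 h and at least 65.6-fold higher. The largest falls were those of Igf2 (-6.13 ± 0.43, detected on 1 of 3 arrays at 48 h) and Ambp (-4.66 ± 0.35, detected on 1 of 3). Apoa2, Ttr and Serpina1b were not detected at 48 h and at least 33.7-, 26.2- and 18.5-fold lower. All 5 are fetal liver cell products.

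All 37 measured genes of nucleolar ribosome biogenesis fell between 0 h and 48 h (37 and 0 adjusted over the list alone), with a median of -1.28, including Ncl (-1.79 ± 0.12), Rrp12 (-1.75 ± 0.12) and Pes1 (-1.71 ± 0.14). The camera adjusted p was 3.28e-13, and 0.0338 with an estimated correlation. Autophagy and organelle clearance genes rose in 18 of 25 cases and fell in 1 (18 and 1 adjusted over the list alone), with Ube2o at 4.50 ± 0.14 and Ube2l6 at 4.34 ± 0.20, at a camera adjusted p of 1.15e-08 and 0.0147 with an estimated correlation. Cell cycle inhibitors rose in 10 of 16 cases and fell in 1 (10 and 2 adjusted over the list alone), with Gadd45a at 5.76 ± 0.12 and Cdkn1a, which codes for p21, at 3.94 ± 0.44 (camera adjusted p = 4.59e-05, and 0.0147 with an estimated correlation). Of 15 heme and iron genes 12 rose and 0 fell (12 and 1 adjusted over the list alone; camera adjusted p = 5.77e-08, and 0.0804 with an estimated correlation). Red cell membrane genes rose in 15 of 17 cases and fell in 2 (15 and 2 adjusted over the list alone; camera adjusted p = 1.47e-06, and 0.0531 with an estimated correlation). Slc4a1 (2.26 ± 0.19), Hbb-bt (2.02 ± 0.30), Cdkn2c (1.96 ± 0.18), Gata1 (1.11 ± 0.15), Ccnd3 (0.78 ± 0.13) and Gata2 (0.52 ± 0.13) rose. Myb (-1.28 ± 0.22) and Ccnd2 (-0.77 ± 0.13) fell, and Myc was at -0.16 ± 0.30 (adjusted p = 0.662). Klf1 (0.47 ± 0.17, adjusted p = 0.0197) and Hba-a1 (0.305 ± 0.11, adjusted p = 0.0242) lost their calls when any of 4 and of 2 arrays was left out. Of 18 erythroid transcription factors 11 rose and 5 fell (11 and 5 adjusted over the list alone) (camera adjusted p = 0.0167, and 0.229 with an estimated correlation). Apoptosis regulators rose in 7 of 18 cases and fell in 1 (7 and 1 adjusted over the list alone) (camera adjusted p = 0.0271, and 0.109 with an estimated correlation).

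Further lists differed less evenly between 0 h and 48 h. DNA replication genes fell in 25 of 33 cases and rose in 2 (25 and 2 adjusted over the list alone; camera adjusted p = 1.12e-05, and 0.114 with an estimated correlation). Myc-regulated metabolism genes fell in 16 of 22 cases and rose in 4 (16 and 4 adjusted over the list alone; camera adjusted p = 0.00674, and 0.0723 with an estimated correlation). Mitochondrial biogenesis genes fell in 23 of 26 cases (24 and 0 adjusted over the list alone; camera adjusted p = 1.86e-06, and 0.0804 with an estimated correlation). Oxidative phosphorylation genes fell in 19 of 35 cases and rose in 2 (19 and 2 adjusted over the list alone; camera adjusted p = 0.0266, and 0.238 with an estimated correlation), and the list's call was lost under 75th percentile scaling (adjusted p = 0.204). Stress response genes rose in 15 of 22 cases and fell in 4 (15 and 4 adjusted over the list alone; camera adjusted p = 3.91e-05, and 0.111 with an estimated correlation). Feedback targets of erythropoietin signalling rose in 8 of 13 cases (8 and 0 adjusted over the list alone; camera adjusted p = 0.00245, and 0.135 with an estimated correlation). Histone acetyltransferases (3 of 12 higher, 4 lower; 3 and 4 adjusted over the list alone) and histone deacetylases (2 of 14 higher, 6 lower; 2 and 6 adjusted over the list alone) had camera adjusted p of 0.953 and 0.372. For the 6 mesenchymal markers (0 higher, 2 lower; 0 and 2 adjusted over the list alone) and the 5 lymphoid markers (1 higher, 2 lower; 1 and 2 adjusted over the list alone) camera gave 0.238 and 0.953. Hepatocyte markers (11 of 15 lower, 1 higher; 11 and 1 adjusted over the list alone; median -2.06, -1.58 at the bounds) had a camera adjusted p of 4.51e-04 and 0.363 with an estimated correlation. Interferon genes (17 of 21 higher; 19 and 0 adjusted over the list alone), macrophage markers (10 of 14; 10 and 0 adjusted over the list alone) and granulocyte markers (10 of 17, 3 lower; 10 and 3 adjusted over the list alone) had camera adjusted p of 9.84e-09, 1.86e-06 and 4.51e-04, and 0.0531, 0.0843 and 0.229 with an estimated correlation. Mast cell and basophil markers (3 of 8 higher, 1 lower; 3 and 1 adjusted over the list alone) had a camera adjusted p of 0.0450 and 0.229 with an estimated correlation. Megakaryocyte and platelet markers (6 of 16 higher; 5 and 0 adjusted over the list alone) had a camera adjusted p of 0.0480 and 0.469 with an estimated correlation, and their call was lost under 75th percentile scaling (adjusted p = 0.0821).

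Cells with moderate GFP had higher levels of nucleolar ribosome biogenesis genes than uninfected cells at 48 h. The median was 0.50 (camera adjusted p = 3.84e-07, and 0.0991 with an estimated correlation). Among erythroid genes, Alas2 (0.01 ± 0.23, adjusted p = 0.972), Slc4a1 (0.11 ± 0.19, adjusted p = 0.705) and Cdkn1b (-0.34 ± 0.19, adjusted p = 0.199) did not pass the test. Nor did Bcl2l1 (-0.42 ± 0.20, adjusted p = 0.114) or Kat2a (0.31 ± 0.19, adjusted p = 0.228). Gata2, a progenitor transcription factor, fell by 0.90. Gata1 (-0.16 ± 0.15, adjusted p = 0.464), Klf1 (-0.20 ± 0.17, 0.404), Hdac2 (-0.04 ± 0.09, 0.771), Ccnd2 (0.03 ± 0.13, 0.879), Ccnd3 (-0.34 ± 0.13, 0.0581), Cdkn2c (-0.41 ± 0.18, 0.0966), Hba-a1 (0.01 ± 0.11, 0.961) and Hbb-bt (0.20 ± 0.30, 0.669) did not pass the test. Ccnd3 and Cdkn2c passed without the third uninfected array (-0.45 and -0.54; adjusted p = 0.0226 and 0.0441), and Bcl2l1 without the third moderate array (-0.64, adjusted p = 0.0205). With the replicate number as a block Bcl2l1 and Ccnd3 passed (adjusted p = 0.0477 and 0.0175). Myb was not detected and at least 1.27-fold lower, a call lost under 75th percentile scaling (adjusted p = 0.0661). Genes of granulocytes, macrophages, mast cells and the interferon response were far lower in the sorted cells. In all 1653 genes were higher and 1287 lower, but of the 910 that differed at least 2-fold 238 were higher and 672 lower. The count of 910 was 450 without background correction and 309 with genes detected on all 15 arrays. The groups did not overlap for 3778 genes, 41.8% (10% by chance). Without the arrays numbered 3, 978 were higher and 994 lower (49.6% higher), and with genes detected on all 15 arrays 1411 and 670, so which direction held more depends on the arrays used. The genes that rose most were Sec14l2, a lipid-binding protein not detected in uninfected cells at 48 h and at least 5.68-fold higher, and Sptb, the beta-spectrin of the red cell membrane (2.99 ± 0.23). Next came Osbpl6, likewise not detected and at least 3.74-fold higher, Tmprss9 (2.69 ± 0.22) and the receptor Notch4 (2.56 ± 0.24), the last 2 detected on 1 of 3 uninfected arrays. Those that fell most were Cstdc4, of the stefin family (-7.27 ± 0.31), and the neutrophil gene S100a9 (-6.60 ± 0.30). Lcn2, Csta2 and the granule protease Ctsg were not detected in the moderate group and at least 50.5-, 59.2- and 60.3-fold lower.

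In the moderate group, 23 of 37 nucleolar genes were higher and 0 lower (25 and 0 adjusted over the list alone), among them Pes1 (0.82 ± 0.14), Bop1 (0.83 ± 0.15) and Nop14 (0.82 ± 0.10). Of 26 genes of mitochondrial biogenesis and import 10 were higher and 0 lower (11 and 0 adjusted over the list alone), for example Timm10 (0.65 ± 0.11), at a camera adjusted p of 0.00195 and 0.279 with an estimated correlation. Oxidative phosphorylation genes were higher in 5 of 35 cases (3 and 0 adjusted over the list alone), with Ndufab1 at 1.22 ± 0.19 (camera adjusted p = 0.0315, and 0.312 with an estimated correlation). Glycolysis went the other way, with 13 of 18 genes lower and 0 higher (14 and 1 adjusted over the list alone). Hk2 fell by 2.09, Pkm by 1.44 and Tpi1 by 1.36 (camera adjusted p = 5.06e-07, and 0.0991 with an estimated correlation). Whether loss of myeloid cells contributes was not tested. Mitosis genes were lower in 10 of 23 cases (11 and 0 adjusted over the list alone) at a camera adjusted p of 0.00132 and 0.0658 with an estimated correlation. Erythroid transcription factors were lower in 6 of 18 cases and higher in 0 (9 and 1 adjusted over the list alone), among them Lmo2 (-0.66 ± 0.11) and Nfe2 (-0.66 ± 0.15). For these camera gave an adjusted p of 0.0419, and 0.331 with an estimated correlation. Myc-regulated metabolism genes had 9 of 22 higher and 3 lower (9 and 4 adjusted over the list alone; camera adjusted p = 0.606), with Cad, the first enzymes of pyrimidine synthesis, at 0.86 ± 0.15. Heme and iron genes (1 of 15 higher, 2 lower; 1 and 2 adjusted over the list alone), membrane genes (3 of 17 higher, 4 lower; 3 and 4 adjusted over the list alone) and globins (2 of 6 higher; 2 and 0 adjusted over the list alone) had camera adjusted p of 0.437, 0.553 and 0.381. Cell cycle inhibitors (3 of 16 higher, 4 lower; 3 and 5 adjusted over the list alone) had 0.652, with Cdkn2b at 2.20 ± 0.20. Autophagy genes (4 of 25 higher, 6 lower; 4 and 6 adjusted over the list alone) had 0.763 with a median of 0.02 and a mean of -0.02, and DNA replication genes (3 of 33 higher, 4 lower; 3 and 3 adjusted over the list alone) had 0.998 with a median of 0.05, a mean of 0.03 and a camera direction of down.

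Markers of other blood cells separated the moderate group from the unsorted cells. Of 17 granulocyte markers 15 were lower and 0 higher (15 and 0 adjusted over the list alone), with a median of -5.27, or -5.08 with 8 undetected genes at their bound (camera adjusted p = 4.81e-24, and 0.0159 with an estimated correlation). Macrophage markers were lower in 12 of 14 cases (12 and 0 adjusted over the list alone), with a median of -2.30 and with Lyz2 at -3.96 ± 0.20 and Adgre1 at -3.71 ± 0.21 (camera adjusted p = 1.30e-12, and 0.0303 with an estimated correlation). Mast cell and basophil markers were lower in 5 of 8 cases (6 and 0 adjusted over the list alone), including Hdc, which makes histamine (-3.63 ± 0.14), with a median of -1.73, -1.37 at the bounds (camera adjusted p = 4.14e-06, and 0.0303 with an estimated correlation). Of 21 interferon response genes 19 were lower and 0 higher (19 and 1 adjusted over the list alone), among them Ifit3 (-3.77 ± 0.22) and Irf1 (-4.08 ± 0.28, detected on 2 of 3 arrays), with a median of -2.09, -1.72 at the bounds (camera adjusted p = 1.47e-16, and 0.0159 with an estimated correlation). Targets of erythropoietin signalling were lower in 4 of 13 cases (4 and 0 adjusted over the list alone; camera adjusted p = 0.0315, and 0.312 with an estimated correlation), and 1 of these 4 is the granulocyte marker Lcn2. Megakaryocyte and platelet markers were higher in 7 of 16 cases and lower in 0 (9 and 0 adjusted over the list alone) (camera adjusted p = 0.0232, and 0.609 with an estimated correlation).

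**Figure D2:**
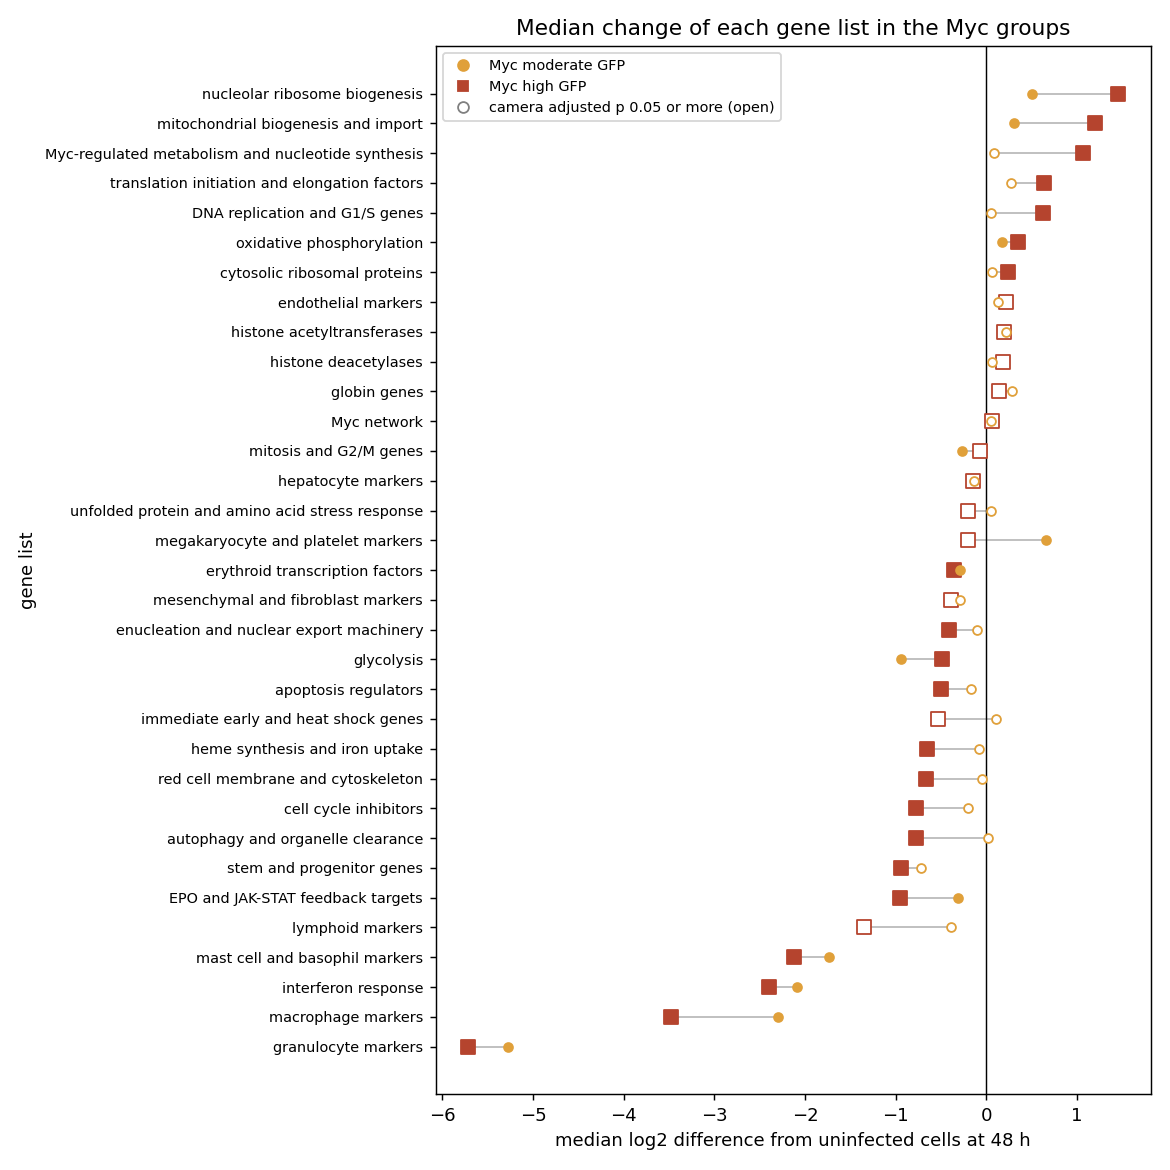
Median log2 difference from uninfected cells at 48 h of each gene list, in the moderate (circles) and high (squares) Myc groups, filled where the camera adjusted p is under 0.05 with the preset correlation, with undetected genes at their fitted values. Nucleolar genes lie at 0.50 and 1.45, megakaryocyte markers at 0.66 and -0.20 and granulocyte markers at -5.27 and -5.71.

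Cells with high GFP, labelled supraphysiological Myc, had lower levels of autophagy, cell cycle inhibitor and enucleation genes than uninfected cells at 48 h. Genes for building ribosomes and mitochondria were higher. Cdkn1b (-2.58 ± 0.19, adjusted p = 1.38e-09), Bcl2l1 (-2.83 ± 0.20, adjusted p = 4.70e-10) and Alas2 (-1.96 ± 0.23, adjusted p = 5.15e-07) were lower. Kat2a, the histone acetyltransferase Gcn5, was higher by 1.16 ± 0.19 (adjusted p = 2.63e-05), Hdac2 by 0.84 ± 0.09 and the cyclin Ccnd2 by 0.87 ± 0.13. In all 2941 genes were higher and 2139 lower (57.9% higher), 2099 by at least 2-fold (964 up, 1135 down), and 5514 genes, 61.0%, had groups that did not overlap (10% by chance). Under 75th percentile scaling 2343 were higher and 2471 lower (48.7% higher), and the median change of all genes went from 0.14 to -0.11. The genes that rose most were Crip2 (3.20 ± 0.13), Wnt2, a secreted signal (2.52 ± 0.20), Arhgap29 (2.46 ± 0.25), the endoplasmic reticulum protein Fkbp11 (2.42 ± 0.15) and Fam83e (2.39 ± 0.28). Wnt2 and Arhgap29 were detected on 2 of 3 uninfected arrays and Fam83e on 1. Those that fell most were Cstdc4 and S100a9, not detected in the high group and at least 360- and 314-fold lower, Stfa1 (-9.08 ± 0.33), S100a8 (-9.07 ± 0.32) and Lyz2 (-7.95 ± 0.20), the last 3 detected on 2, 2 and 1 of 3 arrays of the high group.

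All 37 nucleolar ribosome biogenesis genes were higher in the high group (37 and 0 adjusted over the list alone), with a median of 1.45, among them Nop2 (2.00 ± 0.16), Tsr1 (1.89 ± 0.19) and Nop58 (1.77 ± 0.09). The camera adjusted p was 4.96e-16, and 0.0312 with an estimated correlation. Mitochondrial biogenesis and import genes were higher in 23 of 26 cases and lower in 0 (24 and 0 adjusted over the list alone), including the import proteins Timm9 (1.78 ± 0.12) and Timm10 (1.57 ± 0.11), at a camera adjusted p of 2.57e-08 and 0.0332 with an estimated correlation. Of 22 genes of Myc-regulated metabolism and nucleotide synthesis 13 were higher and 1 lower (13 and 1 adjusted over the list alone). Srm, which makes spermidine, was at 1.69 ± 0.12, and the nucleotide synthesis genes Gart and Cad were at 1.58 ± 0.12 and 1.53 ± 0.15 (camera adjusted p = 2.05e-04, and 0.0312 with an estimated correlation). DNA replication genes were higher in 25 of 33 cases and lower in 3 (25 and 3 adjusted over the list alone) (camera adjusted p = 9.62e-04, and 0.182 with an estimated correlation). Translation factors were higher in 14 of 20 cases and lower in 4 (14 and 4 adjusted over the list alone), with Eif4e, which binds the messenger RNA cap, at 1.36 ± 0.21 and Eif2ak1, the heme-regulated kinase that slows translation, at -1.75 ± 0.16 (camera adjusted p = 0.0121, and 0.128 with an estimated correlation). Oxidative phosphorylation genes were higher in 21 of 35 cases and lower in 1 (21 and 1 adjusted over the list alone; camera adjusted p = 0.00157, and 0.117 with an estimated correlation). Cytosolic ribosomal proteins were higher in 19 of 38 cases (19 and 0 adjusted over the list alone; camera adjusted p = 0.0121, and 0.128 with an estimated correlation), a call that was lost under 75th percentile scaling (adjusted p = 0.201).

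Several lists were lower in the high group. Autophagy and organelle clearance genes were lower in 15 of 25 cases and higher in 0 (15 and 0 adjusted over the list alone), with the mitophagy kinase Pink1 at -2.30 ± 0.14 and Ulk1 at -2.18 ± 0.14. The camera adjusted p was 5.77e-05, and 0.0322 with an estimated correlation. Cell cycle inhibitors were lower in 8 of 16 cases and higher in 1 (8 and 1 adjusted over the list alone), including Ccng2 (-2.09 ± 0.13) and Gadd45a (-2.05 ± 0.12), at a camera adjusted p of 0.00232 and 0.0312 with an estimated correlation. Genes of enucleation and nuclear export were lower in 11 of 22 cases and higher in 4 (11 and 4 adjusted over the list alone; camera adjusted p = 0.0106, and 0.0386 with an estimated correlation). Of its members Tmcc2 was at -3.15 ± 0.24 and Xpo7 at -2.43 ± 0.17, and Vim, a filament protein that white cells also make, was not detected and at least 20.4-fold lower. Heme and iron genes were lower in 8 of 15 cases (8 and 0 adjusted over the list alone; camera adjusted p = 0.00788, and 0.279 with an estimated correlation), with Fech at -1.50 ± 0.13. Membrane and cytoskeleton genes were lower in 12 of 17 cases and higher in 2 (12 and 2 adjusted over the list alone; camera adjusted p = 0.00175, and 0.128 with an estimated correlation), led by the water channel gene Aqp1 (-3.09 ± 0.17). Erythroid transcription factors were lower in 9 of 18 cases and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 0.0164, and 0.203 with an estimated correlation), and this call was lost under 75th percentile scaling (adjusted p = 0.0621). Gata1 (-0.29 ± 0.15, adjusted p = 0.119) and Klf1 (0.02 ± 0.17, adjusted p = 0.914) did not pass the test, while Cbfa2t3, a corepressor, fell by 1.75. Cdkn2c (-0.999 ± 0.18) and Ccnd3 (-0.58 ± 0.13) fell, and Myb was not detected and at least 1.43-fold lower. Slc4a1 was at -0.54 ± 0.19 (adjusted p = 0.0184), a call lost when any of 3 arrays was left out. Hba-a1 (-0.06 ± 0.11, adjusted p = 0.690) and Hbb-bt (-0.60 ± 0.30, 0.0940) did not pass the test, but did under 75th percentile scaling (-0.55 and -0.81; adjusted p = 0.00795 and 0.00742), and Hbb-bt with the replicate block (adjusted p = 6.54e-04). Stem and progenitor genes were lower in 7 of 11 cases and higher in 1 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00371, and 0.128 with an estimated correlation), with Gata2 at -2.40 ± 0.13. Whether loss of myeloid and mast cells contributes here, or for glycolysis genes, was not tested. Apoptosis regulators (10 of 18 lower, 1 higher; 10 and 1 adjusted over the list alone) and glycolysis genes (11 of 18 lower, 3 higher; 11 and 3 adjusted over the list alone) had camera adjusted p of 0.0133 and 0.00928, and 0.0710 and 0.267 with an estimated correlation. The Myc antagonist Mxd1 was not detected in the high group and at least 4.29-fold lower, and the Myc network list (1 of 9 higher, 3 lower; 1 and 3 adjusted over the list alone; camera adjusted p = 0.350) had a median of 0.07, a mean of -0.42 and a camera direction of down.

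Granulocyte, macrophage and mast cell markers were lower in the high group. On all 3 of its arrays 0 of 17 granulocyte, 4 of 14 macrophage and 10 of 16 megakaryocyte and platelet markers were detected. All 17 granulocyte markers were lower (17 and 0 adjusted over the list alone), with a median of -5.71, or -5.12 with 12 undetected genes at their bound (camera adjusted p = 3.43e-15, and 0.0312 with an estimated correlation). Of 14 macrophage markers 13 were lower and 0 higher (14 and 0 adjusted over the list alone), with a median of -3.48, -3.07 at the bounds (camera adjusted p = 2.69e-10, and 0.0312 with an estimated correlation), and Adgre1 was not detected and at least 23.2-fold lower. Megakaryocyte and platelet markers were lower in 3 of 16 cases and higher in 0 (3 and 0 adjusted over the list alone; camera adjusted p = 0.167). Mast cell and basophil markers were lower in 6 of 8 cases (6 and 0 adjusted over the list alone; camera adjusted p = 1.00e-04, and 0.0332 with an estimated correlation). Interferon response genes were lower in 19 of 21 cases and higher in 0 (19 and 0 adjusted over the list alone), with Rsad2 at -5.54 ± 0.21 and a list median of -2.40, the same at the bounds (camera adjusted p = 3.48e-11, and 0.0312 with an estimated correlation). Targets of erythropoietin signalling were lower in 8 of 13 cases and higher in 0 (8 and 0 adjusted over the list alone), with Osm at -2.43 ± 0.37 and Pim1 at -2.01 ± 0.28. These targets had a camera adjusted p of 0.0121 and 0.186 with an estimated correlation.

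Comparing both Myc groups, each sorted and infected, shows which genes went with GFP. The Myc received was not measured, and cell content may differ too. Cdkn1b (-2.24 ± 0.19, adjusted p = 3.66e-08), Bcl2l1 (-2.41 ± 0.20) and Alas2 (-1.98 ± 0.23) were lower in the high group, and Hdac2 (0.88 ± 0.09) and Kat2a (0.85 ± 0.19) were higher. Gata2 (-1.50 ± 0.13) was lower and Ccnd2 (0.84 ± 0.13) higher. Ribosome biogenesis and nucleotide synthesis genes were higher in the high group, and autophagy and cell cycle inhibitor genes were lower. In all 2255 genes were higher and 1726 lower (56.6% higher), 1053 by at least 2-fold (356 up, 697 down). Under 75th percentile scaling 1761 were higher and 2637 lower (40.0% higher), with the median change of all genes going from 0.07 to -0.22. The groups did not overlap for 4751 genes, 52.5% (10% by chance). The genes higher by most were Serpina3b, not detected in the moderate group and at least 2.94-fold higher, Fkbp11 (2.01 ± 0.15) and Crip2 (1.85 ± 0.13). Gata1 (-0.13 ± 0.15, adjusted p = 0.541), Klf1 (0.22 ± 0.17, 0.307), Myc (-0.37 ± 0.30, 0.336), Ccnd3 (-0.24 ± 0.13, 0.153) and Hba-a1 (-0.07 ± 0.11, 0.670) did not pass the test, and Myb was detected in neither group. Under 75th percentile scaling Ccnd3 (-0.33, adjusted p = 0.0412) and Hba-a1 (-0.91, adjusted p = 1.67e-04) passed. Slc4a1 (-0.65 ± 0.19, adjusted p = 0.00785), Cdkn2c (-0.59 ± 0.18, 0.0124) and Hbb-bt (-0.80 ± 0.30, 0.0361) were lower, calls lost when 1, any of 2 and any of 4 arrays were left out. Those lower by most were Gpnmb (-4.82 ± 0.22), the platelet protein gene Ppbp (-4.48 ± 0.40, detected on 2 of 3 arrays of the high group) and Lyz2 (-4.00 ± 0.20, detected on 1 of 3).

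Of 37 nucleolar genes 36 were higher in the high than in the moderate group and 0 lower (36 and 0 adjusted over the list alone), with Nop10 at 1.31 ± 0.10 (camera adjusted p = 1.06e-16, and 0.0143 with an estimated correlation). Myc-regulated metabolism and nucleotide synthesis genes were higher in 17 of 22 cases and lower in 1 (19 and 1 adjusted over the list alone), among them Ppat (1.28 ± 0.13) and Paics, not detected in the moderate group and at least 2.82-fold higher (camera adjusted p = 3.46e-07, and 0.00825 with an estimated correlation). Mitochondrial biogenesis genes were higher in 22 of 26 cases (22 and 0 adjusted over the list alone; camera adjusted p = 9.13e-08, and 0.0631 with an estimated correlation). DNA replication genes were higher in 24 of 33 (28 and 0 adjusted over the list alone; camera adjusted p = 7.66e-06, and 0.148 with an estimated correlation). Autophagy genes were lower in 16 of 25 cases and higher in 1 (16 and 1 adjusted over the list alone), with Ube2o at -2.10 ± 0.14 (camera adjusted p = 3.46e-07, and 0.0143 with an estimated correlation). Cell cycle inhibitors were lower in 10 of 16 cases and higher in 0 (10 and 0 adjusted over the list alone; camera adjusted p = 1.39e-04, and 0.0143 with an estimated correlation), with Cdkn2b at -2.25 ± 0.20. Membrane genes were lower in 10 of 17 cases (11 and 0 adjusted over the list alone; camera adjusted p = 8.78e-05, and 0.122 with an estimated correlation) and heme and iron genes in 7 of 15, with 2 higher (7 and 2 adjusted over the list alone; camera adjusted p = 0.0144, and 0.384 with an estimated correlation). Cytosolic ribosomal proteins were higher in 14 of 38 cases, with a median of 0.15 (14 and 0 adjusted over the list alone; camera adjusted p = 0.0216, and 0.188 with an estimated correlation). Under 75th percentile scaling the median turned to -0.14 and the call was lost (adjusted p = 0.915). Oxidative phosphorylation genes were higher in 15 of 35 cases and lower in 1 (15 and 1 adjusted over the list alone; camera adjusted p = 0.0393, and 0.337 with an estimated correlation). Apoptosis regulators were lower in 7 of 18 cases and higher in 2 (7 and 2 adjusted over the list alone; camera adjusted p = 0.0468, and 0.158 with an estimated correlation), a call lost under 75th percentile scaling (0.0559). Macrophage markers were lower in 10 of 14 cases (10 and 0 adjusted over the list alone; camera adjusted p = 1.88e-05, and 0.148 with an estimated correlation). So were megakaryocyte and platelet markers in 11 of 16 (12 and 0 adjusted over the list alone; camera adjusted p = 5.72e-05, and 0.311 with an estimated correlation) and granulocyte markers in 6 of 17 (6 and 0 adjusted over the list alone; camera adjusted p = 0.0270, and 0.456 with an estimated correlation), with 0 higher in each. Interferon genes were lower in 7 of 21 cases and higher in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0382, and 0.406 with an estimated correlation). Without background correction the granulocyte and interferon calls were lost (adjusted p = 0.0635 and 0.0542).

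A maturation index summed the first day, so it mixes maturation with cell composition. It is the mean log2 level of 463 genes that rose at least 2-fold from 0 h to 24 h minus that of 287 genes that fell. The index was -0.80 ± 0.06 (SD, n = 3) at 0 h, 2.45 ± 0.02 at 24 h and 3.34 ± 0.06 at 48 h in uninfected cells, against 2.78 ± 0.16 in the moderate and 1.75 ± 0.15 in the high group. The moderate group differed from uninfected cells at 48 h by -0.56, the high group by -1.59, and the high from the moderate group by -1.03. The two-sided exact permutation p was 0.1 for each, the smallest for 3 against 3. Without genes of the other cell type and interferon lists, a choice made after seeing the data, the differences were -0.44, -1.51 and -1.07. With genes detected on all 15 arrays the moderate difference was -0.04, and with all called genes whatever their fold it was -0.35. Of the 750 genes, 73.6% had the opposite sign in the high group against uninfected cells at 48 h to that of their change over the first day, and 53.1% in the moderate group. Genes that had risen were lower in 87.7% of cases in the high group and 62.4% in the moderate group, while genes that had fallen were higher in 50.9% and 38.0%. Across all genes first-day change and difference from uninfected cells correlated at Pearson r = -0.40 in the high and -0.19 in the moderate group. Spearman rho was -0.38 and -0.03 (genes are not independent replicates).

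**Figure D3:**
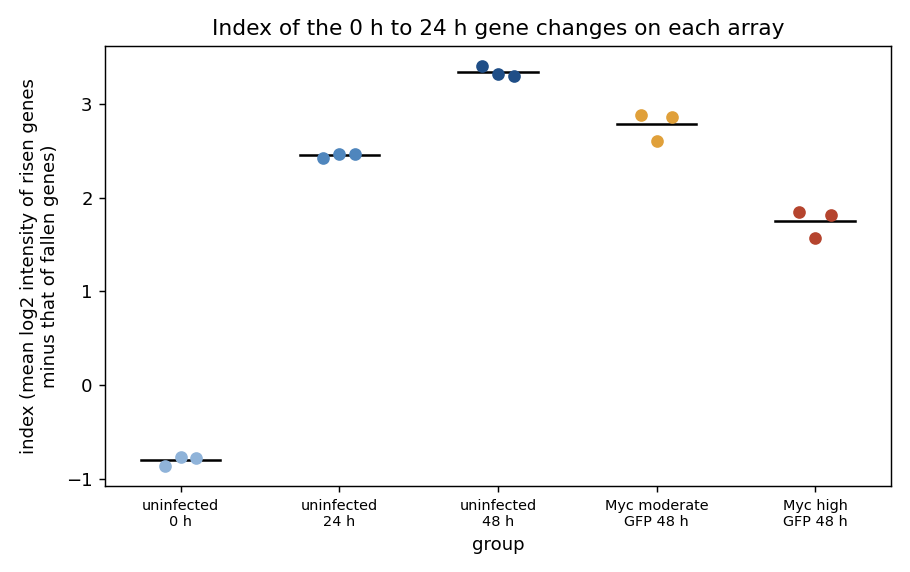
Maturation index (log2 units) of each of the 15 arrays by group, with points for single arrays and a line at each group mean (n = 3). Uninfected cells climb from -0.80 at 0 h to 3.34 at 48 h, and the moderate and high groups sit lower, at 2.78 and 1.75.

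Both Myc groups shared many genes in their difference from uninfected cells at 48 h. There were 1070 genes higher in both and 1057 lower in both, where independent lists of these sizes would share 537.4 and 304.3. The differences correlated across genes at r = 0.79 (0.50 simulated) and had the same sign for 71.7% (66.6% simulated). Simulations with the same 3 uninfected arrays gave a covariance of 0.02 (0.69 observed), which argues against noise in them as the main source of the excess. Without the arrays numbered 3, 661 genes were higher in both, and with genes detected on all 15 arrays 500 were lower in both. In contrast, 162 genes went in opposite directions in the 2 groups, 131 of them higher in the moderate and lower in the high group.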

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

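The tests in this part were chosen only after the result was seen, except the counts over other splits of the arrays and the list tests of the high against the moderate group. Several gene lists changed differently in the second day of culture than in the first, by a camera test of the difference itself. The median of the difference (24 h to 48 h minus 0 h to 24 h) was -1.03 for DNA replication and G1/S genes (adjusted p = 1.57e-15, adjusted p = 0.0205 with an estimated correlation) and -0.74 for mitosis and G2/M genes (2.12e-07 and 0.0202). For globin genes it was -0.84 (0.0448 and 0.474), for stem and progenitor genes 0.75 (0.00377 and 0.174) and for immediate early and heat shock genes 0.94 (0.0211 and 0.514). Megakaryocyte and platelet markers had 0.73 (0.0010 and 0.393) and endothelial markers 1.25 (8.40e-04 and 0.145), a difference largely fixed beforehand, since 3 of 10 endothelial markers were still detected on all arrays at 24 h and the others had little room to fall further. The Myc groups also differed, by the test of the high against the moderate group. The median was -0.89 for autophagy and organelle clearance (3.46e-07 and 0.0143) and for megakaryocyte and platelet markers (5.72e-05 and 0.311). There were 162 single genes higher in one Myc group and lower in the other.

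Myeloid markers were lower in both Myc groups than in uninfected cells at 48 h: S100a9 had a log2 level of 13.64 in uninfected cells at 48 h, 7.03 in the moderate and 4.68 in the high group, and Lyz2 had 13.19, 9.23 and 5.24. The GFP sort may have removed uninfected myeloid cells, which the CD11b depletion at the start of culture should already have lowered. The granulocyte median was -5.27 in the moderate group, but sort and infection separate the same arrays, so removal cannot be told apart from an effect of Myc. Repression in proportion to the Myc level also stays open, with a median of -1.64 between the high and the moderate group over 12 markers detected on all moderate arrays, a filter that favours a fall, and of -0.35 over all granulocyte and -0.83 over all macrophage markers, since a higher GFP gate could also hold fewer such cells. Of the 17 granulocyte and 14 macrophage markers 1 and 0 are on another list, and 11 and 10 were detected on all 3 arrays of the progenitors at 0 h.

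Interferon response genes rose from 24 h to 48 h in uninfected cells and were lower in both Myc groups. Transcripts carried at a constant level by myeloid cells would have moved with myeloid markers, but the mean rise of the interferon genes (2.15) exceeded that of granulocyte markers (0.99) by 1.16 (SE 0.20) and that of macrophage markers (0.75) by 1.41, which argues against this explanation. Repression in proportion to the Myc level may contribute and stays open, with a median of -1.09 between the high and the moderate group over 8 genes detected on all moderate arrays, a filter that favours a fall, and of -0.20 over all 21 (-0.46 at the bounds). Sort and infection separate the same arrays here too.

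The Myc probe differed little over the 5 groups. An exchange of the high group's arrays with those of uninfected cells at 48 h would place their nucleolar means the wrong way round, yet the lowest high array lay 1.34 above the highest uninfected array, against a largest SD within a group of 0.107, which argues against it. A probe that does not read the retroviral transcript may give the flat signal: the difference was 0.067 (adjusted p = 0.867), and this stays open because the sources used here do not give the sequence of the transferred gene.

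Each comparison's count was set beside the 10 splits of its 6 arrays into 3 and 3, all 15 arrays fitted. In each of the 6 comparisons 1 of the 10 splits, the real one, gave as many genes: 2943 for 24 h against 0 h, 3399 for 48 h against 24 h, 5243 for 48 h against 0 h, 2940 for the moderate and 5080 for the high group against uninfected cells, and 3981 between the Myc groups. The others gave 0, but mix both groups, so the test cannot decide. Nor can 10 splits give a share under 0.05.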

How the results depend on the processing

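The alternative without all arrays numbered 3 and the index without other cell type and interferon lists were chosen after seeing the data. Over 11 alternatives the number of genes called ranged from 2395 to 3736 for 24 h against 0 h, 2951 to 3835 for 48 h against 24 h, 4001 to 5656 for 48 h against 0 h, 2081 to 3412 for the moderate and 3839 to 5506 for the high group against uninfected cells, and 3317 to 4561 between the Myc groups. The counts of genes changed at least 2-fold depend more on the processing: in the same order they were 360, 362, 1201, 450, 1141 and 469 without background correction, 482, 463, 1568, 596, 1451 and 644 with an offset of 50 (a larger offset shrinks folds by construction), and they were lower too with detection on all 15 arrays. Leaving out arrays gave 1794 to 2771, 2384 to 3172, 4323 to 5064, 1972 to 2719, 4267 to 4869 and 2859 to 3813, the lowest of each without all arrays numbered 3, and 661 to 1097 genes higher in both Myc groups, where fewer arrays leave less power. The index difference of the high group from uninfected cells was -1.40 without background correction, -1.32 under 75th percentile scaling, -1.37 with an offset of 50 and -1.31 with all called genes. The high group differed from the moderate group by -0.79 under 75th percentile scaling, and the moderate group from uninfected cells by -0.35 with all called genes (the cause was not tested). With detection on all 15 arrays, which leaves 5779 genes to test, these differences were -1.36, -1.31 and -0.043, the opposite-sign share of the high group was 81.9%, and 500 genes were lower in both Myc groups. Single genes changed sign in Rpl37 (0.062) and Atp5b (0.031) for 24 h against 0 h under 75th percentile scaling, and in Acta2 with the authors' values (0.057 in the moderate and 0.17 in the high group), and the cause was not tested. Of the named genes, 75th percentile scaling ended 27 calls and gave 5, the authors' values ended 4, and leaving out 1 array ended 209 and gave 3 over all arrays left out. For lists, 75th percentile scaling ended 6 calls and gave 6, an estimated correlation ended 66, and fry gave 50 and ended 1.

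The replicate numbers were tested as a pairing: 23 of 30 pairs of arrays with the same number in 2 groups correlated above 0.1 after removal of group means (0.00930 to 0.470). Same-number pairs had a median of 0.197 and other pairs -0.114, and 15 of 15 arrays correlated best with their own number, a hint from the data and not from the design. All 3 pairs exceeded 0.1 for 24 h and 48 h, 0 h and 48 h and the 2 Myc groups, but not for the other comparisons. With the number as a replicate block the counts were 3380, 3835, 5598, 3412, 5403 and 4371. The block gave 6 list calls, those of globin, enucleation and glycolysis genes for 48 h against 0 h (adjusted p = 0.0485, 0.0485 and 0.0495) and of stem and progenitor, translation and enucleation genes in the moderate group (0.0471 each). It ended 1, that of apoptosis regulators between the Myc groups (0.0513), and gave the calls of 4 named genes: Hbb-bt for 48 h against 24 h and in the high group, and Bcl2l1 and Ccnd3 in the moderate group. A block by slide was not run, since the files used here give no slide. Signal over background limits genes near the floor, whose changes are understated.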

Other observations

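All tests in this part, its gene groups and its comparison with uninfected cells at 24 h were chosen after the values were seen. Of 3 such gene groups 2 differed between the Myc groups and uninfected cells at 48 h by the preset correlation only. Aminoacyl-tRNA synthetases, the enzymes that charge transfer RNA with amino acids, were higher in 9 of 18 cases and lower in 0 in the moderate group against uninfected cells at 48 h, with Wars at 0.98 ± 0.19 and Lars at 0.92 ± 0.12 (unadjusted camera p = 6.28e-04, p = 0.107 with an estimated correlation). In the high group 12 of 18 were higher and 1 lower, with Rars at 1.25 ± 0.11 (unadjusted camera p = 0.00717, p = 0.194 with an estimated correlation). Proteasome subunits, which degrade proteins tagged with ubiquitin, were higher in 18 of 34 cases and lower in 3 in the moderate group (0.00213 and 0.102) and in 21 and 3 in the high group (0.00116 and 0.0859), where Psmd7 was at 1.29 ± 0.10. The interferon-induced subunit Psmb9 went the other way, at -2.88 ± 0.21 and -2.89 ± 0.21. Between the high and the moderate group the same test gave 0.470 for synthetases and 0.0866 for proteasome subunits. For the third group, 54 histone genes, the unadjusted camera p was 0.948 in the moderate and 0.702 in the high group, with medians of 0.001 and 0.23.

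A hypothesis is that cells with high GFP were held in the state of the 24 h culture, since several genes that changed from 24 h to 48 h lay near the 24 h level. Against uninfected cells at 24 h Cdkn1b differed by 0.06 (confidence interval -0.35 to 0.47), Bcl2l1 by 0.15, Alas2 by -0.12 and Hdac2 by 0.06, and 8 of 14 lists called for 48 h against 24 h had medians within 0.3 of their 24 h level. Nucleolar genes, however, lay a median of 0.76 above their 24 h level (adjusted p = 0.0234 with an estimated correlation) and Kat2a 0.67 above it (adjusted p = 0.00866). These values argue against a plain hold at 24 h.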
